A study of Homo sapiens with 6 samples.

How the data were processed

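H3K4me3 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7 cells with an antibody against the trimethyl mark. Per the labels' protocols, cells that carried an inducible hairpin were kept for 72 h in medium with 10% hormone-stripped serum, and hairpin expression was induced for 72 h at 100 ng/ml of an inducer that the labels do not name. Cells were crosslinked, lysed and sonicated, per the labels' protocols. The series describes 6 samples, of which 4 are H3K4me3 libraries, 2 for the control hairpin (ShCtrl) and 2 for the MEN1 hairpin (ShMEN1). The 2 input libraries, 1 per condition, were not analysed here. Groups and replicate numbers were taken from the sample titles.

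Per the submitters' processing notes, Bowtie and MACS2 were used with the hg19 genome build. Versions and settings are not given in the sources used here, nor is the library that served as the background of each peak list. The authors deposited 1 peak list per library, so replicates were not pooled. Each list has no header and holds chromosome, start, end, a peak name and a score. Lengths in base pairs come from the starts and ends, which are printed here 1-based. The deposited score column has no name. Its lowest values lie just above 2 (2.02 to 2.16), so it may be a log-scaled significance, but its kind is not stated, so scores of different lists may not be on one scale. An exact two-sided permutation test of the list medians between groups gave p = 0.333, the smallest possible. The score was otherwise used to rank and filter peaks within a list, and for the fit of score levels described below, which also gives the enrichment that a score stands for if it is such a significance. The shortest peak in each list is 200 bp and the smallest gap between peaks is 77 bp. Read counts are not part of the lists, so the depth of each library is unknown and no counting interval is given. The precision of every value rests on 2 libraries per group.

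Peaks of the 4 lists were merged into regions where they shared at least 1 bp. For every region and library, the called width was the summed length of that library's peaks in the region. A region was called ShCtrl-only or ShMEN1-only when both libraries of one group and neither of the other had a peak there. Its counts were set beside those of the other 2 divisions of the libraries into pairs. Widths were compared on the log2 scale over regions with a peak in all 4 libraries with limma 3.58.1 in R 4.3.3, with eBayes and a trend, without centring and without a replicate block. No pseudocount was needed because every tested width was above 0. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Library-level values were compared by exact two-sided permutation tests in scipy 1.17.1 under Python 3.11.15. Sets of regions were compared by permuting region labels. Merging and overlap gave the same totals as bedtools 2.31.1. Tested on simulated data, the merging step recovered 30 of 30 planted ShCtrl-only and 50 of 50 planted ShMEN1-only regions. The simulated lists were slightly shifted copies of a single list without its closely spaced peaks, so this checks the counting only. In 5 simulated runs of the width comparison over 16754 regions, limma called 21.2% of regions changed by 0.3 on the log2 scale, 62.4% of those changed by 0.6, 97.6% of those changed by 1.2 and 100.0% of those changed by 2, with 10.4 false calls per run. The simulated widths were independent and normal, with the spread estimated by the fit itself and equal numbers of changes up and down. They held no widening common to most regions, so these rates may not apply to the real lists.

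The regions named in the text followed a rule fixed before the data were examined, as were the tests of peak number, covered length, Jaccard overlap, presence and width and most alternative settings. Named were up to 12 narrower and 12 wider regions with the largest change past the threshold, the 8 ShCtrl-only and 8 ShMEN1-only regions with the highest mean score percentile, and the 8 widest regions. The rule also named MEN1 and members of the gene lists, which were not analysed here. Regions with a mean width of at least 4000 bp, the ordering of widths by library, the spacing and chromosome tests and the fit of score levels were chosen after the data were seen. For that fit, scores between 4 and 16 were compared with the levels of a Poisson tail probability, with a tolerance of 0.02, and the background that placed most peaks on the levels was kept. That background placed 34.6% to 39.6% of these peaks on its levels, and the background of the other group 18.5% to 24.3%.

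The peak lists are on hg19, and the gene table used here is on GRCh38, so regions are given by position and not by gene. Planned comparisons that need an annotation of hg19 were not made. These were the promoters that differ between groups, the promoter share of such regions, and the widths at 17 gene lists. The mark at MEN1 itself is not analysed here, and the peak lists do not show how far the hairpin lowered MEN1 RNA. Alternatives covered stricter and equal-length lists, the merging distance, the measure of width, a width filter, centring, the trend, a replicate block and leaving out each library. The same-numbered libraries share only a number in the labels.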

Results

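H3K4me3, the trimethyl mark on lysine 4 of histone H3 that sits mainly at active promoters, was mapped by ChIP-seq in MCF-7, an established estrogen receptor positive breast cancer cell line. The cells carried an inducible small hairpin RNA against MEN1 (ShMEN1) or a control hairpin (ShCtrl). MEN1 encodes menin, a subunit of KMT2A and KMT2B histone methyltransferase complexes that write this mark. The comparison asks how the genome-wide distribution of H3K4me3 differed after the MEN1 hairpin was induced. The MEN1 locus itself is not analysed here. Each group held 2 libraries, each with its own peak list. The lists held 20083 peaks for ShCtrl 1, 19924 for ShCtrl 2, 20066 for ShMEN1 1 and 20208 for ShMEN1 2. Read numbers are not part of the peak lists, so the sequencing depth behind each peak is unknown. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

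The number of H3K4me3 peaks was close in the 2 groups, while the length of genome they covered was larger in both ShMEN1 libraries. Peaks numbered 20003.5 ± 112 in ShCtrl and 20137 ± 100 in ShMEN1 (mean ± SD, n = 2 each), and the groups overlapped. Peaks covered 21.0 ± 0.12 Mb in ShCtrl and 23.2 ± 0.015 Mb in ShMEN1, a difference of 10.5%. The median peak was 870 ± 13.4 bp long in ShCtrl and 965 ± 13.4 bp long in ShMEN1. Neither covered length nor median length overlapped between groups. An exact two-sided permutation test gave p = 0.333 for both, the smallest p that 2 libraries against 2 allow. The exact test gave p = 0.667 for the number of peaks. The median peak score, the authors' own value within each list, was 36.2 and 36.1 in the ShCtrl lists and 48.5 and 46.1 in the ShMEN1 lists. The commonest scores followed the levels of a Poisson background of 0.65 reads in both ShCtrl lists and 0.88 reads in both ShMEN1 lists. Whether this level comes from the ChIP libraries or from an input and its scaling is not known.

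Peak sets were more alike within a group than across groups. The base-pair Jaccard index, which is the shared length divided by the joint length, was 0.880 for the 2 ShCtrl lists and 0.895 for the 2 ShMEN1 lists. The 4 pairs across groups lay between 0.835 and 0.842. Mean overlap within groups exceeded that between groups by 0.0487. The other 2 ways to pair the libraries gave -0.0238 and -0.0248. These values cancel the first by construction, so they are no separate contrast.

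Most regions carried the mark in every library, and the regions called in both libraries of one group and in neither of the other were mainly short and weak. Merging overlapping peaks of the 4 lists gave 20032 regions, of which 16754 (83.6%) had a peak in all 4 libraries. A peak in both ShMEN1 libraries and in neither ShCtrl library was found at 662 regions, called ShMEN1-only below. The opposite pattern, ShCtrl-only, was found at 107 regions. ShMEN1-only regions thus made up 3.65% of regions called in both ShMEN1 libraries, and ShCtrl-only regions 0.627% of those called in both ShCtrl libraries. When the libraries were paired across groups instead, the corresponding counts were 81 and 78 for one pairing and 56 and 56 for the other. These pairings mix the groups, so they cannot show a difference in calling that both lists of a group share. Such a difference, as in the fitted background, was not told apart from a change in the mark at the ShMEN1-only regions. No p-value is given, since only 3 pairings exist. The median called length was 300 bp at ShMEN1-only regions, 260 bp at ShCtrl-only regions, and 1064 bp at shared regions in the ShCtrl lists. The median ShMEN1-only region stood at the 9.03 percentile of peak scores in its own lists, and the median ShCtrl-only region at the 7.42 percentile. When only peaks at or above the median score of their list were compared, the counts were 359 ShMEN1-only and 232 ShCtrl-only regions, against at most 96 for the other pairings, but 0 regions reached the median score in both lists of one group and had no peak at all in the other. Merging peaks within 500 bp gave 386 ShMEN1-only and 60 ShCtrl-only regions. With ShCtrl 1, ShCtrl 2, ShMEN1 1 or ShMEN1 2 left out, so that 1 library stood for its group, the counts were 1011, 1079, 1247 and 1234 for ShMEN1-only and 303, 312, 238 and 201 for ShCtrl-only regions.

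**Figure D1:**
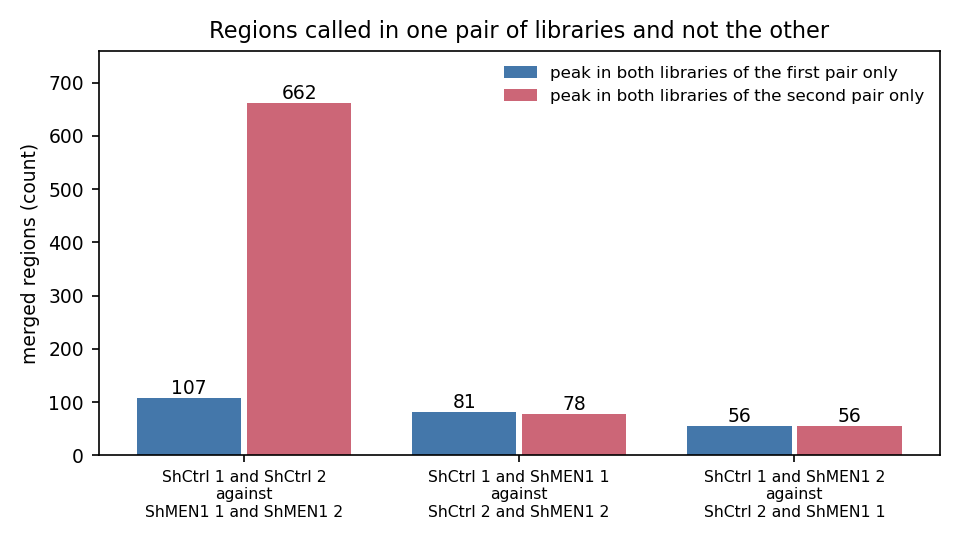
Bars count merged regions (y axis) with a peak in both libraries of one pair and in neither library of the other, for the 3 ways to divide the 4 libraries into pairs (x axis). The division by group gave 107 ShCtrl-only and 662 ShMEN1-only regions, and the other divisions gave 56 to 81. The other divisions mix the groups and cannot show a difference in calling shared by both lists of a group.

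The strongest ShCtrl-only regions included 2 neighbours on chromosome 7. One spanned 156514922 to 156517402 (hg19 throughout), with 2470 and 2471 bp called in the ShCtrl libraries, and the other spanned 156513803 to 156514622, with 609 and 760 bp. They lay 112 and 299 bp from the nearest other region. Over these regions and their surroundings, from 156511922 to 156520402, called peaks covered 3685 ± 28.3 bp in ShCtrl and 308 ± 38.2 bp in ShMEN1 (SD, n = 2). Each ShMEN1 library thus still held 1 peak in this window. Another region on chromosome 7, from 16920557 to 16921543, had the highest mean score percentile of all ShCtrl-only regions, 34.1, and a called length of 911 ± 86.3 bp in ShCtrl. It lay 591 bp from another region. Other long ShCtrl-only regions lay on chromosome 4, from 39543421 to 39545556 (1724 ± 442 bp), and on chromosome 7, from 107988410 to 107989707 (1115 ± 260 bp). Their nearest other regions were 11857 and 86166 bp away. The remaining 3 of the 8 highest-ranked ShCtrl-only regions were 251 to 282 bp long on average and lay on chromosomes 2, 6 and 9. Their nearest other regions were 52154, 179 and 14514 bp away, in that order. In all, 3 of the 107 ShCtrl-only regions were longer than 1000 bp, and 2 scored above the 25th percentile of their lists.

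The strongest ShMEN1-only region lay on chromosome 1, from 177225900 to 177228238, with 2042 and 2339 bp called in the ShMEN1 libraries and no other region within 74864 bp. It stood at the 36.6 percentile of scores in its lists. On chromosome 7, the ShMEN1-only region from 132260736 to 132261725 held 915 ± 43.8 bp, with no other region within 503857 bp. Other high-ranking ShMEN1-only regions lay on chromosome 3 from 185827136 to 185827713 (540 ± 53.7 bp), chromosome 12 from 53615031 to 53615540 (506 ± 6.36 bp), chromosome 17 from 7306850 to 7307393 (520 ± 33.9 bp), chromosome 4 from 53577983 to 53578404 (395 ± 5.66 bp) and chromosome 2 from 130635378 to 130635741 (328 ± 39.6 bp), each 186 to 541 bp from another region. The remaining one of the 8 highest-ranked, on chromosome 1 from 234811866 to 234812194, held 291 ± 1.41 bp. Only 4 of the 662 ShMEN1-only regions were longer than 1000 bp.

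ShMEN1-only regions differed from shared regions in their spacing and not detectably in their spread over chromosomes. Of the ShMEN1-only regions, 327 (49.4%) lay within 1 kb of another region, compared with 37.7% of the shared regions, and 105 (15.9%) lay over 100 kb from any other, compared with 13.3%. A permutation test over regions gave p = 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 4e-05 over the 4 tests of this family. For ShCtrl-only regions the shares were 48.6% and 8.41%, with a permutation p of 0.107 and an adjusted p of 0.213. Their share within 1 kb was close to that of the ShMEN1-only regions, but they were fewer (107 against 662). Nearness to another region was thus not particular to ShMEN1-only regions, and other regions missing in some libraries were not compared. For the distribution over chromosomes, the permutation test gave an adjusted p of 0.513 for each set. Regions are not independent replicates, so these tests compare the lists and not the treatments.

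Regions shared by all 4 libraries were wider in the ShMEN1 lists. The median shared region was 82.5 bp longer in ShMEN1, a median log2 width change of 0.11 or 1.08-fold. Both ShMEN1 widths exceeded both ShCtrl widths at 8844 regions (52.8%), and both lay below at 1261 regions (7.53%). Each ordering is expected at 16.7% of regions by chance, and the other pairings of the libraries gave 9.05% to 10.3%. The shares of the other pairings fall as those of the groups rise, so the reference is 16.7%. With each library centred on its median log2 width, 3332 regions were wider and 5872 narrower. This centring moved widths by 0.14, more than the median change of 0.11, so it turned the direction by construction. With centring on the median ratio to the region mean the numbers were 4397 and 4456. The SD of the log2 width difference between the 2 libraries of a group was 0.24 for ShCtrl and 0.20 for ShMEN1, and the medians of these differences were 0.0071 and -0.0011. By genomic coordinate, the mean added length was 48.7 bp at the left edge, 48.0 bp at the right edge and 10.6 bp in gaps inside regions. Regions were not oriented by gene, so these means cannot show whether single regions widened symmetrically. Of 1191 regions split into several peaks in both ShCtrl libraries, 558 (46.9%) were a single peak in both ShMEN1 libraries. The reverse held at 115 of 439 regions (26.2%). Over the 23 chromosomes with at least 100 shared regions, median widening ranged from 0.07 on chromosome 14 to 0.14 on chromosome 19 on the log2 scale. The fitted background, a single value per list, was also higher in both ShMEN1 lists and so divided the libraries in the same way. It was not fitted by chromosome or region.

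**Figure D2:**
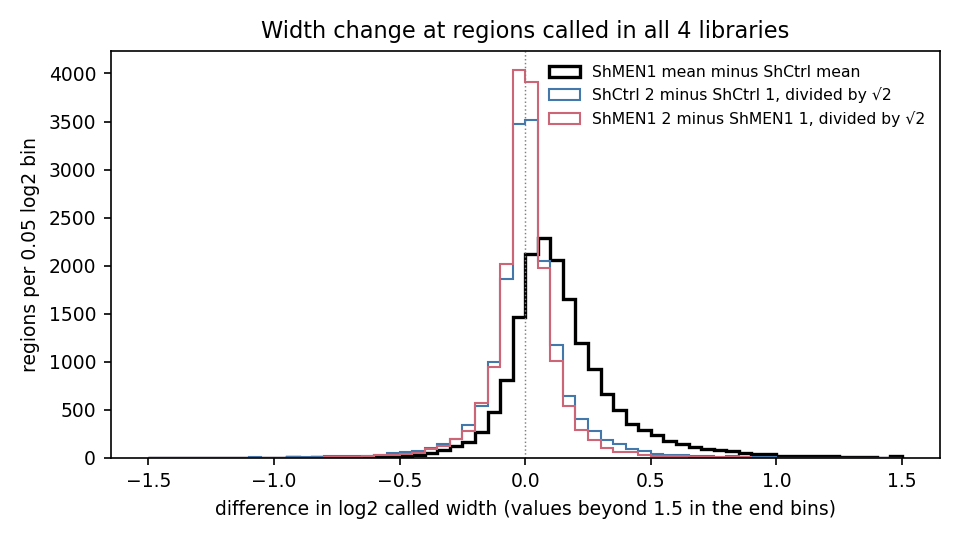
Histograms over the 16754 shared regions of the difference in log2 called width (x axis). The y axis gives regions per bin of 0.05, with values beyond the axis in the end bins. Black shows the ShMEN1 mean minus the ShCtrl mean. Blue (ShCtrl) and red (ShMEN1) show replicate 2 minus replicate 1 within the group, both divided by the square root of 2. The black curve has its median at 0.11, and the replicate differences have medians close to 0.

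Widening in relative terms was largest at narrow regions, and in base pairs at broad ones. Shared regions were divided by mean width into 10 classes of nearly equal size. In class 2, from 412 to 575 bp, the median change was 12.5% or 57.0 bp, and in class 10, from 2362 bp upward, it was 4.84% or 141 bp. The 8 widest regions, which held 6966 to 19212 bp of called peaks on average, differed between groups by 0.09 or less on the log2 scale, and none passed the test. Their log2 changes as called were -0.0047 to 0.09, most of them positive. Centring libraries on their median ratio to the region mean lowers every region by the same amount, larger than any of these changes. After it, all 8 therefore had negative log2 changes, -0.11 to -0.01, by construction. The widest lay on chromosome 10, from 8086955 to 8107253, with 18903 ± 134 bp in ShCtrl and 19522 ± 99.7 bp in ShMEN1 (limma, adjusted p = 0.294). No single peak in any list was longer than 11854 bp, so this width sums several peaks in each library. The next widest region was on chromosome 11, from 65265218 to 65275747, with 10499 ± 30.4 bp and 10518 ± 13.4 bp (adjusted p = 0.955). A region on chromosome 2, from 227656469 to 227665889, measured 9368 ± 50.9 bp and 9347 ± 24.7 bp (adjusted p = 0.943). One on chromosome 14, from 38057026 to 38066192, measured 8327 ± 280 bp and 8878 ± 278 bp (adjusted p = 0.218). The other 4 lay on chromosomes 15, 3 and 12, where chromosome 12 held a pair of them. Among 148 regions with a mean width of at least 4000 bp, 82 were wider and 19 narrower in both ShMEN1 libraries. Their median log2 change was 0.05, below the 0.11 of all shared regions. Of these broad regions, 8 passed the test as wider and 0 as narrower.

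**Figure D3:**
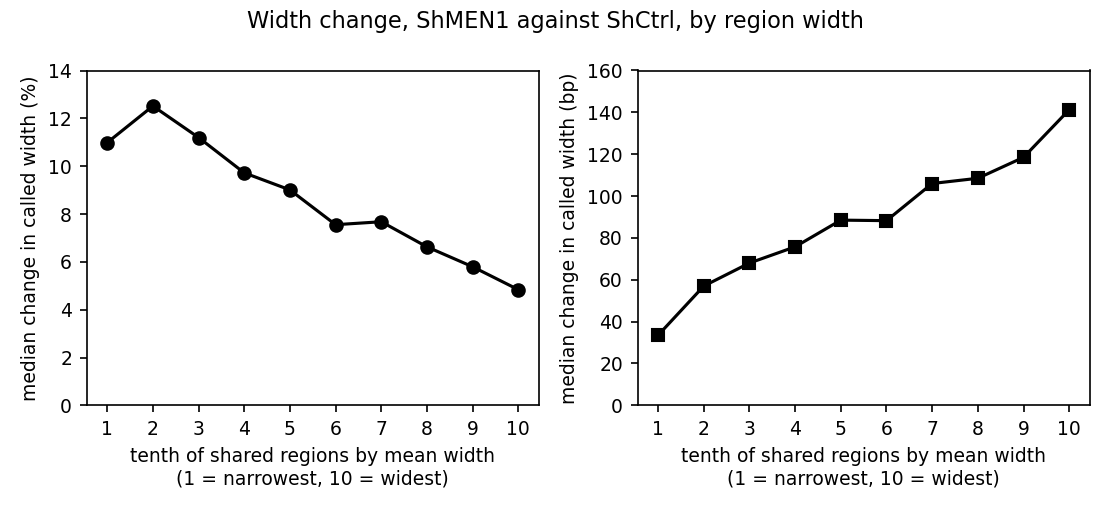
Points give the median change in called width, ShMEN1 against ShCtrl, in percent (left) and in bp (right), for 10 classes of shared regions ordered from narrowest to widest mean width (x axis). The change was 12.5% in class 2 and 4.84% in class 10, and it went from 33.5 bp in class 1 to 141 bp in class 10.

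Region by region, 381 shared regions were wider and 11 narrower in ShMEN1 at an adjusted p below 0.05 (limma with a mean-variance trend on log2 width, Benjamini-Hochberg adjustment over 16754 regions). The calls, including those of the regions named here, were lost with either centring, without the trend and without any 1 library. The wider regions had a median log2 change of 0.56 and were found on 23 chromosomes, and 58 of them more than doubled. The largest widening was on chromosome 3, from 174581737 to 174583396, where called width rose from 232 ± 44.5 bp to 1595 ± 13.4 bp (log2 change 2.80 ± 0.16 SE, adjusted p = 0.0259 in limma). The short peaks of the 2 ShCtrl libraries in this region did not overlap each other. It was followed by chromosome 5 from 138727709 to 138729053, with 265 ± 11.3 bp and 1205 ± 198 bp (2.18 ± 0.15, adjusted p = 0.0305), and chromosome 8 from 25903033 to 25904063, with 237 ± 33.2 bp and 932 ± 46.0 bp (1.98 ± 0.15, adjusted p = 0.0360). The other 9 of the 12 largest lay on chromosomes 1, 2, 4, 9, 11, 14, 22 and X, with chromosome 2 represented by a pair, and their log2 changes were 1.53 to 1.83. Among these 9, the region on chromosome 2 from 161055715 to 161056887 went from 369 ± 17.7 bp to 1121 bp, and that on chromosome 9 from 125226285 to 125227414 went from 371 ± 6.36 bp to 1071 ± 20.5 bp. All 12 had a mean ShCtrl width of 232 to 371 bp, where the shortest peaks of the lists were 200 bp.

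Of the 11 narrower regions, 8 had a mean width of 1477 bp or more over the 4 libraries. The largest narrowing was on chromosome 4, from 135118221 to 135121256, where called width fell from 2933 ± 146 bp to 1247 ± 185 bp (log2 change -1.24 ± 0.11 SE, adjusted p = 0.0379). This region held a single long peak in each ShCtrl library and several shorter ones in each ShMEN1 library. Width also fell on chromosome 10 from 102105906 to 102110842, with 4599 ± 229 bp and 3271 ± 120 bp (-0.49 ± 0.05, adjusted p = 0.0426), and on chromosome 11 from 100996023 to 101000488, with 4168 ± 17.7 bp and 3325 ± 89.8 bp (-0.33 ± 0.03, adjusted p = 0.0430). On chromosome 17, from 13502248 to 13506066, width fell from 3460 ± 211 bp to 2474 ± 22.6 bp (-0.48 ± 0.05, adjusted p = 0.0449). A region on chromosome 6, from 116380447 to 116382354, fell from 1786 ± 148 bp to 1169 ± 8.49 bp, and one on chromosome 11, from 14664840 to 14667255, from 2290 ± 41.7 bp to 1739 ± 10.6 bp. The others were on chromosome 1 from 151344195 to 151345209, chromosome 9 from 110267416 to 110268551, chromosome 19 from 44860920 to 44861930, and chromosome 7 from 45614161 to 45616230 and from 116139138 to 116140945. Their log2 changes were between -0.89 and -0.36.

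**Figure D4:**
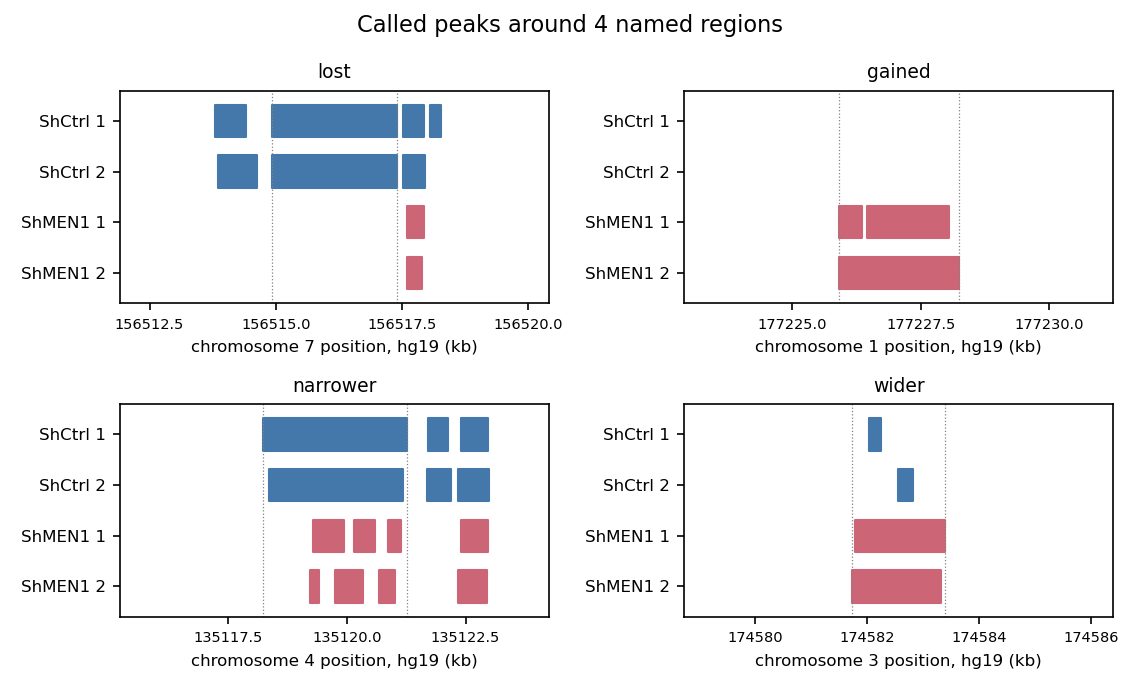
Bars mark called peaks in each library (blue, ShCtrl; red, ShMEN1) along hg19 position in kb around a ShCtrl-only region (panel lost), a ShMEN1-only region (panel gained) and the regions with the largest narrowing and widening past the test, with dotted lines at the edges of the named region. The window on chromosome 7 held 3705 and 3665 bp of called peaks in the ShCtrl libraries and 335 and 281 bp in the ShMEN1 libraries.

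The adjusted p-values of the 392 calls lay between 0.0259 and 0.0496, and the adjustment allows 19.6 false ones among them, more than the 11 narrower calls. The numbers of wider and narrower calls were 577 and 52 of 16754 regions for the longest single peak. They were 604 and 18 of 14193 with peaks merged within 500 bp, and 367 and 31 of 8347 for peaks at or above the median score. For mean widths of at least 1000 bp they were 580 and 16 of 9425. Limma gave 0 calls with each library centred on its median log2 width (3561 regions at an unadjusted p below 0.05, of which 2152 were narrower), centred on its median ratio to the region mean (3065), without the trend (3953), and without ShCtrl 1 (4050), ShCtrl 2 (4410), ShMEN1 1 (2694) or ShMEN1 2 (2689). Of the 3065 regions after centring on the median ratio, 1265 were narrower and 1800 wider, against 258 and 4098 without centring. That centring lowers the log2 change of every region alike, to 2.69 at the chromosome 3 region and -1.35 at the chromosome 4 region. With that centring, 26.6% of regions were narrower and 26.2% wider in both ShMEN1 libraries, where 16.7% is expected by chance for each. The other pairings of the libraries gave at most 2003 regions ordered one way, against 4456 for the groups. Those numbers fall as the group numbers rise, so they are no separate reference.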

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

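The centring on the median ratio to the region mean, the ordering of widths, the 500 bp length filter and the score filter that kept 562 ShMEN1-only regions were chosen after seeing the data, and the other alternatives were planned. The direction of the group difference in covered length, Jaccard overlap and median log2 width was kept in all alternatives run for them, with 0.09 to 0.12 for the median log2 width change. The difference in peak number was 54 to 213 without 1 library, and keeping a fixed share of each list leaves its sign set by the list lengths. The numbers of ShCtrl-only and ShMEN1-only regions were 232 and 359 for peaks at or above the median score of each list, 60 and 386 when peaks within 500 bp were merged, 10 and 64 for regions over 500 bp, and 0 and 0 when both lists of a group had to reach their median score with no peak in the other. Without 1 library, when 1 list alone stands for its group, they ranged from 201 to 312 and from 1011 to 1247. The numbers of narrower and wider regions past the adjusted threshold in limma were 31 and 367 for peaks at or above the median score, 18 and 604 with merging within 500 bp, 52 and 577 for the longest single peak, and 16 and 580 for mean widths of at least 1000 bp. They were 0 and 0 after median centring (3561 regions with an unadjusted p below 0.05), after centring on the median ratio (3065), without the trend (3953), and without any 1 library, where the lone library was assumed to vary like the other group. With a replicate block they were 0 and 0 as well (4131 at an unadjusted p below 0.05). The deviations of same-numbered libraries correlated at -0.0427, and the labels give no shared batch, so the block is not read as a pairing. The division by group gave 4356 regions at an unadjusted p below 0.05 in limma, where 837.7 are expected by chance. The other 2 divisions of the libraries gave 166 and 205 such regions and no adjusted call. In those divisions the group difference adds to the spread within pairs and lowers the counts, so they are not a chance rate. Regions narrower and wider in both ShMEN1 libraries numbered 5872 and 3332 after median centring, and 4456 and 4397 after centring on the median ratio. For mean widths of at least 1000 bp they numbered 669 and 5318 of 9425 regions (7.10% and 56.4%). For peaks at or above the median score they numbered 606 and 4500 of 8347 regions (7.26% and 53.9%). As called, the shares were 7.53% and 52.8% of 16754 regions, so under these filters the counts fell with the number of regions. The median centring moved widths by 0.14 on the log2 scale, more than the median change of 0.11. Leaving out a library loosens the presence rule for its group, and the length filter removes regions by construction. For the other settings, apart from the ordering of widths under the width and score filters, the cause was not tested. Centring on the median ratio moves every region by less than the smallest change among the named narrower and wider regions, 0.33 in size on the log2 scale, so it could not turn their sign, and their adjusted p was above 0.05 after it. The changes of the 8 widest regions, -0.0047 to 0.09 as called, were -0.11 to -0.01 on that scale. The alternatives for gene promoters, gene lists and promoter share were not run, since no hg19 annotation was used here. Unknown read depth limits all of these values.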

Other observations

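The tests of explanations and of neighbouring regions below were chosen after the results were seen, except that of a trend with region width, whose prediction was written first. After removal of the overall widening, the groups still parted in the relative widths of shared regions. With each of 10 width classes centred separately, 25.8% of regions were wider and 26.2% narrower in both ShMEN1 libraries. Each ordering is expected at 16.7% by chance. The other pairings of the libraries gave at most 12.1%, but their shares fall as those of the groups rise, so they are no separate reference.

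The overall widening in the ShMEN1 lists has a technical candidate explanation in the background level behind the calls, which may come from the depth of the ChIP libraries or from the input of each condition and its scaling. The commonest low scores fit the steps of a Poisson background, and the fitted level was 0.88 reads in both ShMEN1 lists against 0.65 in both ShCtrl lists, a ratio of 1.35. At these levels a score of 2 corresponds to an enrichment of 7.95 over background in ShMEN1 and 9.23 in ShCtrl, so longer and weaker stretches may pass in ShMEN1. Joining of split peaks is argued against as the main source, since regions with a single peak in all 4 libraries had a median log2 width change of 0.10. A wider mark after MEN1 silencing remains possible for the median change of 0.109 over all shared regions and cannot be told apart from the background level, because both divide the 4 libraries in the same way.

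At 562 of 662 ShMEN1-only regions, both ShMEN1 peaks reached the score of 4.38 that stands for the enrichment needed in the ShCtrl lists. These regions were selected as called in ShMEN1, so this does not show that the ShCtrl lists could have called them.

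The change in relative widths was weighed against a trend with region width. Narrow regions widened more in percent, but centring within width classes left 25.8% of regions wider in both ShMEN1 libraries. This was above the bound of 20% set beforehand for a cause other than the trend. The bound set for the trend lay below the 16.7% expected by chance, so the test could not have favoured the trend. With 3 divisions of 4 libraries, no share of divisions can fall below 0.05. A dependence of called width on the shape of each region's flanks at different read depth was not tested, and a biological difference between the hairpins stays open as well.

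Both ShMEN1 lists carry the same prefix in their peak names, and the numbers in the prefixes of the ShCtrl lists are the reverse of their replicate numbers. A single library deposited under both ShMEN1 labels is argued against by the intervals, of which 10, or 0.0498% of ShMEN1 1, were identical, compared with 19 for the ShCtrl pair. Technical replicates of a single culture remain possible and were not tested.

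Of the 107 ShCtrl-only regions, 6 had another such region within 50 kb, compared with a median of 2 (95% range 0 to 6) in 2000 random draws from the 3278 regions missing in at least 1 library (one-sided permutation p = 0.0710, adjusted p = 0.0710). For ShMEN1-only regions the number was 82, compared with 63 (44 to 84, permutation p = 0.0430, adjusted p = 0.0710).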
